A study of Homo sapiens with 8 samples.

How the data were processed

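MicroRNA levels were measured in A549 cells, an established human lung adenocarcinoma line, with 1-colour Agilent microarrays, 1 array per culture labelled a biological replicate. The labels assign 4 arrays to non-irradiated cells (0 Gy) and 4 to cells given gamma rays at 2 Gy, all taken 24 h after the irradiation. Per the labels' protocols, control cells went through the same handling apart from the irradiation, dishes were kept on ice before and after exposure, and total RNA was labelled with Cy3. Each array held 2549 human miRNAs with 20 spots per miRNA, spread over 1 to 4 probes.

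Per the file headers, the spots were read with Agilent Feature Extraction 12.0.0.7, which subtracted the background, set outlier flags and called each miRNA detected or not. The deposited scanner values are intensities per spot on a linear scale, not normalized between arrays, and can lie below 0 after background subtraction. The same software's total intensity per miRNA and its 0 or 1 flags were deposited with them. A second table from the authors holds normalized linear intensities of 333 miRNAs, which are those detected on 5 or more arrays, and leaves 101 values empty. Its normalization is not given in the sources used here. Its column medians ran from 14.1 to 18.2, and each column correlated with the total signal of its array at 0.995 or above across miRNAs, on the log2 scale, with a shift that changed with intensity. The scale is linear and the direction the same as that of the scanner values, while its centring stays unknown. It was used only as an alternative.

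From the scanner files, control spots (2164 per array) and spots with an outlier flag (3.11% to 4.53% of the miRNA spots) were left out. The background-subtracted intensity was divided by the 75th percentile of each array over the 377 of 5893 probes that were well above background, in over 0.5 of their spots, on all 8 arrays, and multiplied by the geometric mean of these percentiles. Values under 26.9 were then set to that floor (4.75 on the log2 scale), the median over arrays of the 5th percentile among spots well above background, and log2 was taken. Log2 values of spots were averaged per probe, and a miRNA is the mean over its probes well above background on all arrays, or over all its probes where none was. No spot was saturated, and no pair of arrays held identical signals. Tested were the 299 miRNAs detected on all 4 arrays of at least 1 group, of which 273 were detected on all 8 arrays. The number of arrays limits the precision.

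Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3), irradiated minus non-irradiated, two-sided, with Benjamini-Hochberg adjustment over the 299 miRNAs and a threshold of 0.05. Intervals are 95% limits of the fit. Of 18 lists fixed before the data were examined, 13 had at least 3 tested members and were tested with camera at the preset correlation of 0.01, adjusted over the 13 lists. Camera with an estimated correlation and fry stand beside it. The lists were p53-linked miRNAs, the miR-17 to miR-92 clusters, the let-7, miR-200, miR-29, miR-30 and miR-15 and miR-16 families, the miR-23, miR-27 and miR-24 clusters, regulators of DNA repair genes, inflammation and NF-kB, the miR-99, miR-100 and miR-125 clusters, the miR-221, miR-222 and miR-181 families, the 14q32 imprinted cluster, markers of blood, of muscle, of endothelium and fibroblasts, and of neural tissue and liver, and probes known to follow RNA quality. The level of a list on an array is the mean of its tested members minus the mean of all tested miRNAs, compared by an exact permutation test. That measure was chosen after the data had been seen. Values per array (number of miRNAs detected, brightness, control spots) were compared by exact permutation tests over 70 reassignments, two-sided, where the smallest possible p is 0.0286.

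The rule for the miRNAs named in the text was fixed before the data were examined. It takes every miRNA past the adjusted threshold, up to 12 per direction with the smallest unadjusted p where fewer pass, up to 4 members of each list by unadjusted p, the 10 with the highest mean signal, and 8 chosen by name (miR-34a, miR-210, miR-21, miR-27a, miR-24, miR-16, let-7a and miR-200c). MiR-18a-5p, miR-30b-5p, miR-99a-5p, the markers of other cell types, the arms of hairpins and the miRNAs along the main axis of variation were named outside this rule, after their values were seen.

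The procedure was tested on simulated data for the same comparison, with 299 miRNAs, 40 of them changed, in 50 rounds. With independent noise, limma recovered 18.8% of changes of 0.25 log2 units, 47% of those of 0.5, 79.4% of those of 1 and 94% of those of 2, and 4.24% of its calls were false. In unchanged data camera called 0.154% of the lists with independent noise, and 18.8% of them when the main axis of variation between the real arrays was added to the noise. With that axis 8.05% of the limma calls were false, above the 5% aimed at, and 17%, 49.2%, 79.2% and 96.6% of the changes of these sizes were recovered.

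Alternatives fixed beforehand were 4 other scalings or summaries (the 75th percentile over all probes, quantile normalization, centring on the median of the tested miRNAs, the software's total signal per miRNA), normexp background correction with an offset of 50, the authors' table, 2 other detection filters, a lower floor, the replicate number as a block, eBayes with trend or robust, and leaving out each array in turn. The normexp setting used the median spot signal, since the files used here hold no mean spot signal. Further ones were added after the data had been seen, namely the main axis of variation as a covariate, array weights, and leaving out both arrays numbered 4. A block by slide or scan was not run, as all 8 arrays lay on 1 slide and were read in 1 scan. The planned measure from probes for viral miRNAs was not run, as none was found among the probes. Robust eBayes and the covariate were run for single miRNAs and not for lists. The arrays of the non-irradiated group filled 1 row of the slide and those of the irradiated group the other, so slide row and group cannot be told apart. Coordinates are not given, since the annotation at hand belongs to another genome build than the file headers name. Figures were drawn with matplotlib 3.10.9.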

Results

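MicroRNA profiles were obtained from A549 cells, a human lung adenocarcinoma line, 24 h after gamma irradiation at 2 Gy or after the same handling at 0 Gy. The comparison asked how widely miRNAs respond to a dose of the size given per day in fractionated radiotherapy, in a line described as radioresistant in clonogenic assays. Each group comprised 4 arrays from replicates labelled as biological. Of 2549 human miRNAs on the array, 2146 were detected on no array, 273 on all 8, and 130 on some. The number detected per array ran from 311 to 371. It was 333 ± 21.6 (SD, n = 4) in irradiated and 345 ± 28.8 (SD, n = 4) in non-irradiated cells, a difference of -12 (exact permutation p = 0.543, two-sided, smallest possible p 0.0286). The raw 75th percentile of the signal was 376 ± 53.9 in irradiated and 444 ± 61.0 in non-irradiated cells (SD, n = 4, exact permutation p = 0.143). The median of the negative control spots was -0.107 ± 0.292 and 0.292 ± 0.481 (SD, n = 4, exact permutation p = 0.229). The smallest exact permutation p, 0.0571, was that of the hybridization spike-in signal. It was 3.92 ± 0.036 in irradiated and 3.99 ± 0.043 in non-irradiated cells (log10, SD, n = 4). Among the 7 such measures per array the lowest adjusted p was 0.4.

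No single miRNA passed the adjusted threshold 24 h after 2 Gy. The closest were higher miR-99b-5p, a member of the miR-99 and miR-100 family, higher miR-221-3p, which targets the cell cycle inhibitor CDKN1B, and lower miR-21-3p, the minor arm of the miR-21 hairpin. The log2 level of miR-99b-5p was 7.24 ± 0.055 in irradiated and 6.90 ± 0.054 in non-irradiated cells (SD, n = 4), a log2 change of 0.34 ± 0.059 (SE, limma adjusted p = 0.161), which was 0.19 with quantile normalization and 0.18 in the authors' table. MiR-221-3p stood at 7.72 ± 0.066 against 7.28 ± 0.15 (SD, n = 4), a 1.35-fold difference (limma adjusted p = 0.187). MiR-21-3p stood at 8.43 ± 0.055 against 8.79 ± 0.14 (SD, n = 4), a log2 change of -0.36 ± 0.084 (SE, limma adjusted p = 0.275). In each of these 3 the 4 irradiated arrays lay apart from the 4 non-irradiated ones, whereas the adjusted p did not reach 0.05.

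The largest absolute log2 change among the 299 tested miRNAs was that of miR-210-3p, the main miRNA induced by hypoxia, at 0.71 (95% interval 0.29 to 1.12, limma adjusted p = 0.275). Its level was 5.82 ± 0.36 in irradiated and 5.11 ± 0.14 in non-irradiated cells (SD, n = 4), with irradiated replicate 1 at 6.36 and the rest of its group at 5.59 to 5.71. Without that array the change of miR-210-3p was 0.53, and with normexp background correction it was 0.36. MiR-4284 was higher by 0.50 (limma adjusted p = 0.373), with irradiated replicate 4 at 11.2 and the others at 10.6 to 10.7, and without that array the change was 0.35. With the software's total signal it was 0.29, and 0.32 in the authors' table.

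**Figure D1:**
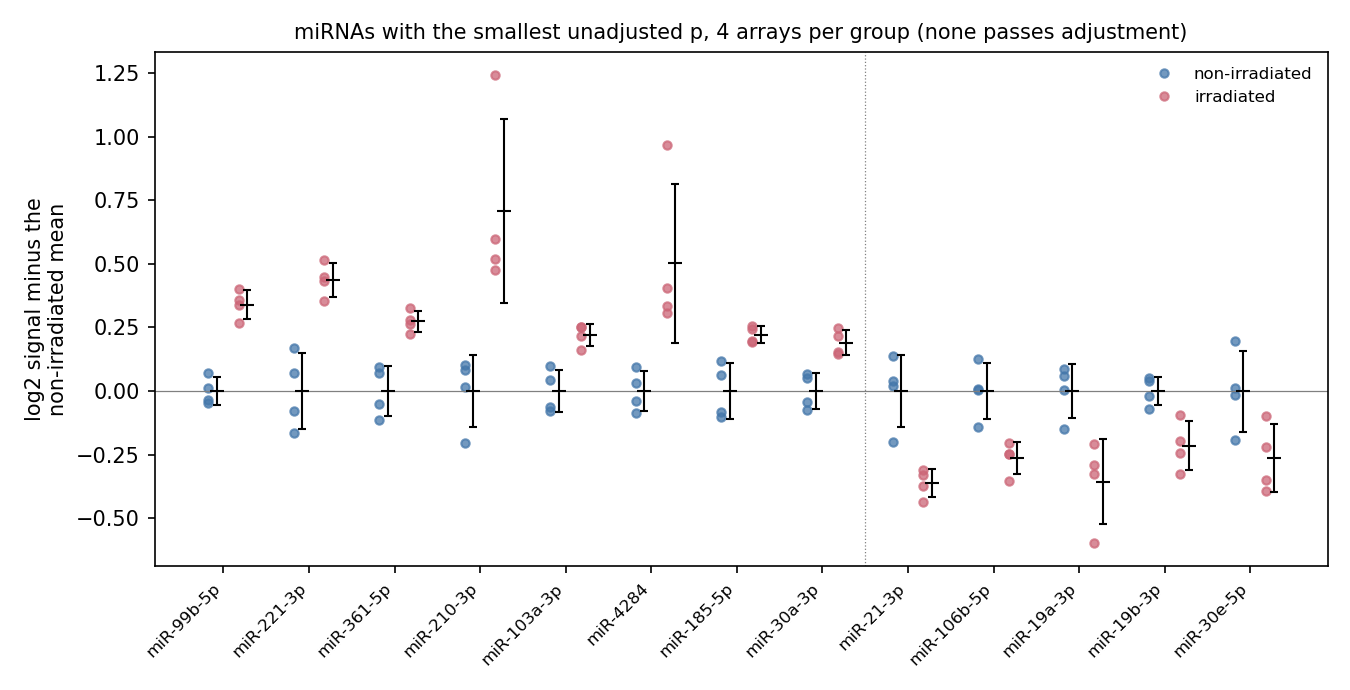
Log2 signal of 13 miRNAs on each of the 8 arrays, as the difference from the mean of the non-irradiated group (vertical axis, log2 units); points are arrays, bars the mean and SD of 4 arrays, and the dotted line parts the 8 with higher from the 5 with lower means in irradiated cells. MiR-99b-5p changed by 0.34 and miR-21-3p by -0.36 with no overlap between the groups, while irradiated replicate 1 lies apart in miR-210-3p, and no miRNA shown passed the adjusted threshold.

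The remaining miRNAs with the smallest unadjusted p in the higher direction had log2 changes from 0.19 (miR-30a-3p) to 0.33 (miR-7114-5p). They were miR-361-5p, miR-103a-3p, miR-185-5p, miR-30a-3p, miR-3659, miR-7114-5p, miR-1268b and miR-181b-5p, with limma adjusted p of 0.275 to 0.423. The change of miR-185-5p was 0.22, and -0.0047 in the authors' table. The others stayed above 0 in every alternative but shrank in some. Their lowest values were 0.040 for miR-30a-3p, 0.11 for miR-103a-3p, 0.13 for miR-361-5p and 0.15 for miR-3659. For miR-7114-5p the lowest was 0.16, and for miR-1268b and miR-181b-5p it was 0.17. In the lower direction, miR-106b-5p (-0.26), miR-19a-3p (-0.36), miR-19b-3p (-0.21) and miR-30e-5p (-0.26) were among the 5 with an unadjusted p under 0.05, together with miR-21-3p. MiR-140-3p, miR-25-3p, miR-15a-5p, miR-17-3p, miR-30e-3p, miR-320d and miR-16-5p followed at -0.13 to -0.38, with unadjusted p above 0.05. With normexp background correction the changes of miR-140-3p and miR-30e-3p turned to 0.010 and 0.067. In that setting 258 of all 299 tested miRNAs were above 0 and 41 below, against 219 and 80 as reported. Turns upward there are thus not particular to these miRNAs.

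By limma, 0 of 299 miRNAs passed adjustment and 22 had an unadjusted p under 0.05, of which 17 were higher and 5 lower, where chance gives 14.95. The groups did not overlap for 16 miRNAs (12 higher and 4 lower), where chance gives 2.86% of them, or 8.54. Among the 16 were miR-149-5p (0.024) and miR-744-5p (0.099), with 93.5% and 72.4% of spots at the floor. Values at the floor limit what such a gap shows. No absolute log2 change exceeded 1. Of the 299 tested miRNAs 219 had a log2 change above 0 and 80 below, and with centring 138 and 161. Counts of list members above or below 0 are to be read against that share. The median log2 change over all tested miRNAs was 0.096 and fell to -0.011 when arrays were centred on the tested miRNAs, so levels of lists are given below relative to the median of all. The split of the unadjusted calls moved with the scaling as well. It was 6 higher and 8 lower with quantile normalization, 10 and 10 with the software's total signal, 5 and 9 in the authors' table, and 4 and 2 with centring. Simulated changes of 1 log2 unit were recovered at the adjusted threshold in 79.4% of cases, of 0.5 in 47% and of 0.25 in 18.8%. In that simulation 40 of 299 miRNAs changed in each round. The adjustment is stricter where fewer miRNAs change, which was not simulated, so these shares can be too high for sparse changes. All 4 irradiated arrays lay in 1 row of the slide and all 4 non-irradiated ones in the other, so slide row and irradiation cannot be told apart.

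Among the lists of related miRNAs, the miR-17 to miR-92 clusters had the smallest p in camera, in the lower direction. These paralogous clusters promote proliferation and hold miR-17-5p, miR-19a-3p, miR-19b-3p, miR-20a-5p and miR-92a-3p, with miR-106b-5p, miR-93-5p and miR-25-3p in the cluster within MCM7. Of 11 tested members 10 had a log2 change below 0, with miR-18a-5p at 0.051, and the changes ran down to -0.36. The list median was -0.19, which is -0.28 relative to the median of all tested miRNAs, and -0.15 without non-irradiated replicate 4 and -0.18 without irradiated replicate 1. Camera gave an adjusted p of 2.58e-07, but adjusted p = 0.172 with an estimated correlation, and fry gave an adjusted p of 0.146 (0.0489 in its mixed test, which takes changes in either direction). Over all tested miRNAs 0 members passed, and adjusted over the list alone 2 did, miR-106b-5p and miR-19a-3p (lowest adjusted p 0.0463). The list level per array was 0.85 ± 0.17 in irradiated and 1.09 ± 0.20 in non-irradiated cells (SD, n = 4), with arrays of the groups overlapping (exact permutation p = 0.114). On the same arrays the level of the RNA quality probes was 0.24 ± 0.25 against 0.14 ± 0.38 (SD, n = 4, exact permutation p = 0.686).

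The miR-30 family, linked to the restraint of autophagy and of epithelial to mesenchymal change, was the other list called lower by camera (adjusted p = 0.0289, and adjusted p = 0.172 with an estimated correlation). All 5 members had changes below 0, from -0.015 for miR-30b-5p to -0.26 for miR-30e-5p, with miR-30a-5p at -0.088, miR-30d-5p at -0.057 and miR-30c-5p at -0.062. The median was -0.16 relative to all tested miRNAs (-0.25 without non-irradiated replicate 3 and -0.25 without irradiated replicate 4), and its own sign turned to 0.013 with normexp background correction. The list level was 0.29 ± 0.16 against 0.48 ± 0.24 (SD, n = 4, exact permutation p = 0.257). Directions of single members were not stable. Over the alternatives miR-30c-5p ran from -0.20 to 0.063 and miR-30d-5p from -0.21 to 0.026. MiR-30b-5p stood at 7.53 on non-irradiated replicate 4, against 6.86 to 7.02 on the rest of its group. Its mean in irradiated cells was 7.09, so its direction rests on that array. The call ended without non-irradiated replicate 4 (adjusted p = 0.0989) and without irradiated replicate 2 (adjusted p = 0.0592), and over the alternatives the adjusted p ran from 1.06e-13 to 0.239. In simulated data without any change, camera called 18.8% of lists when the arrays shared the real main axis of variation, which bears on both calls.

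**Figure D2:**
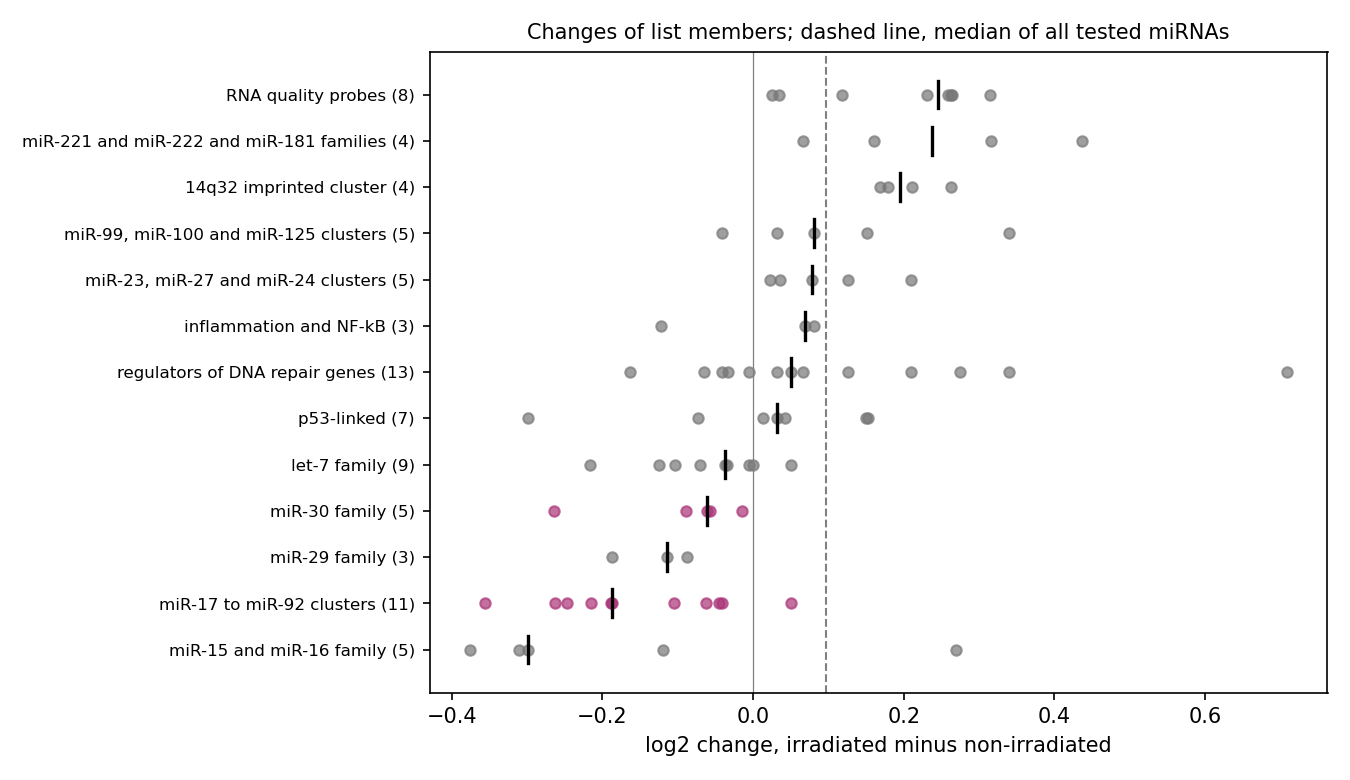
Log2 change (irradiated minus non-irradiated, horizontal axis) of each tested member of the 13 lists with 3 or more tested members, given in brackets; black bars are list medians, the dashed line is the median of all tested miRNAs (0.096), and the lists in purple are the 2 called by camera. The 11 members of the miR-17 to miR-92 clusters and the 5 of the miR-30 family lie left of the dashed line. So do all members of the let-7 (9), miR-29 (3) and inflammation and NF-kB (3) lists, which camera did not call.

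The miR-15 and miR-16, miR-29 and let-7 families had medians below 0 without passing camera. The miR-15 and miR-16 family, which limits cyclins and BCL2, had 4 of 5 members below 0, among them miR-15a-5p at -0.38, miR-424-5p at -0.31 and miR-16-5p at -0.30, and miR-503-5p at 0.27 (list median -0.40 relative to all, camera adjusted p = 0.0785). The miR-29 family, which targets collagen transcripts, had all 3 members below 0, from -0.19 for miR-29a-3p to -0.087 for miR-29b-3p, with miR-29c-3p at -0.11 (camera adjusted p = 0.0517). Over the alternatives miR-29a-3p ran from -0.29 to -0.10, miR-29c-3p from -0.22 to -0.049 and miR-29b-3p from -0.19 to 0.037. The let-7 family, repressors of RAS and MYC, had 7 of 9 below 0 and a median of -0.13 relative to all (camera adjusted p = 0.0882). Its named members were let-7g-5p at -0.22, let-7a-5p at -0.12, let-7i-5p at -0.070 and let-7c-5p at 0.050. With normexp miR-15a-5p was at -0.16. Single arrays weighed on several of these members. Without non-irradiated replicate 4 the change was -0.081 for miR-424-5p, -0.034 for let-7g-5p and 0.061 for let-7a-5p. Without non-irradiated replicate 3 these were -0.47, -0.35 and -0.26, and without irradiated replicate 1 they were -0.18, -0.063 and -0.028. For let-7g-5p and let-7a-5p the changes were -0.10 and -0.020 without irradiated replicate 2, -0.33 and -0.21 without irradiated replicate 3, and -0.37 and -0.24 without irradiated replicate 4. Adjusted over the list alone, 0 members of these 3 families passed, as over all miRNAs.

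On the higher side, the miR-221, miR-222 and miR-181 families had all 4 tested members above 0, at 0.44 for miR-221-3p, 0.32 for miR-181b-5p, 0.16 for miR-222-3p and 0.067 for miR-181a-5p. Their median was 0.14 relative to all (camera adjusted p = 0.0515), with 3 members above the median of all and 1 below. MiR-181a-5p turned to -0.075 with quantile normalization. Over the alternatives miR-222-3p ran from 0.019 to 0.27 and miR-181b-5p from 0.17 to 0.44. Adjusted over the list alone 1 member passed, miR-221-3p. The 4 tested members of the 14q32 imprinted cluster were also above 0, at 0.26 for miR-494-3p, 0.21 for miR-376a-3p, 0.18 for miR-487b-3p and 0.17 for miR-376c-3p. Leaving out 1 array in turn moved miR-494-3p between -0.24 and 0.64. For the 4 members camera gave an adjusted p of 0.0715. Fry, which asks whether the members move one way and not whether they differ from other miRNAs, gave 0.0166. Of the spots of miR-376a-3p 56.4% lay at the floor, 35.6% for miR-376c-3p, and miR-494-3p is also among the RNA quality probes.

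MiRNAs with an established part in the radiation response showed no change past adjustment. MiR-34a-5p, a direct target of p53, stood at 8.57 ± 0.14 in irradiated and 8.41 ± 0.34 in non-irradiated cells (SD, n = 4), a log2 change of 0.15 with a 95% interval from -0.24 to 0.55 (limma adjusted p = 0.877). The change of miR-34a-5p was 0.31 without non-irradiated replicate 4, 0.042 without non-irradiated replicate 3 and 0.097 without irradiated replicate 4. It was 0.045 with centring, 0.059 with the percentile over all probes and 0.079 with the software's total signal. Among the 7 tested p53-linked miRNAs 5 were above 0 and 2 below, with miR-22-3p at 0.15 and miR-194-5p at 0.043. Against the median of all tested miRNAs 5 of the 7 lay below and 2 above. The list median of 0.032 turned negative with all-probe scaling (-0.061), and in camera the list leaned lower (adjusted p = 0.510) although its median and mean were above 0. Of 13 tested regulators of DNA repair genes 8 were above 0, the largest changes being those of miR-210-3p, miR-99b-5p, miR-138-5p at 0.27 and miR-24-3p, which targets the histone H2AX transcript, at 0.21. Against the median of all tested miRNAs, however, 8 of the 13 lay below and 5 above. Camera gave an adjusted p of 0.436, and the list median of 0.051 became -0.067 with quantile normalization. Fry's mixed test gave an adjusted p of 0.00518. Adjusted over the list alone 2 members passed, miR-99b-5p and miR-210-3p. The change of miR-138-5p ran from 0.12 to 0.37 over the alternatives.

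The miR-99, miR-100 and miR-125 clusters had 4 of 5 members above 0, which besides miR-99b-5p were miR-125a-5p at 0.15, miR-125b-5p at 0.081 and miR-100-5p at 0.032, and miR-99a-5p below 0 at -0.041 (camera adjusted p = 0.218, fry's mixed test adjusted p = 0.0135, 1 of 5 passing adjusted over the list alone). Against the median of all tested miRNAs 3 of these 5 members lay below and 2 above. The changes of miR-100-5p and miR-125b-5p turned to -0.062 and -0.012 with the percentile over all probes. The miR-23, miR-27 and miR-24 clusters had all 5 members above 0, with miR-27a-3p at 0.13, miR-23a-3p at 0.078, miR-23b-3p at 0.036 and miR-27b-3p at 0.023 (camera adjusted p = 0.510). Of these 5, however, 3 lay below the median of all tested miRNAs. With the percentile over all probes miR-23a-3p, miR-23b-3p and miR-27b-3p turned to -0.015, -0.058 and -0.071, and the list median from 0.078 to -0.015. Of the inflammation list 3 members were tested, miR-21-5p at -0.12, miR-31-5p at 0.069 and miR-125b-5p (camera adjusted p = 0.510). In camera this list leaned lower although its median was 0.069, and the median turned to -0.025 with that percentile, as did miR-31-5p.

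None of the 10 miRNAs with the highest mean signal passed adjustment. MiR-21-5p, an abundant miRNA of many carcinomas, stood at 14.4 ± 0.083 in irradiated and 14.5 ± 0.15 in non-irradiated cells (SD, n = 4, limma adjusted p = 0.805). The other 9 were miR-7975, miR-7977, miR-5100, miR-7641, miR-494-3p, miR-1260b, miR-8069, miR-1260a and miR-27b-3p, with log2 changes from 0.023 to 0.27 and limma adjusted p of 0.805 to 0.934. The changes of miR-7975, miR-5100, miR-1260a and miR-27b-3p turned below 0 under at least 1 other scaling. Over all alternatives miR-1260b ran from 0.083 to 0.37, miR-494-3p from -0.24 to 0.64 and miR-7641 from -0.36 to 0.72. Within groups miR-7641 and miR-494-3p varied most of these, with SDs of 1.12 and 0.952 in irradiated and 1.18 and 1.01 in non-irradiated cells (n = 4).

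**Figure D3:**
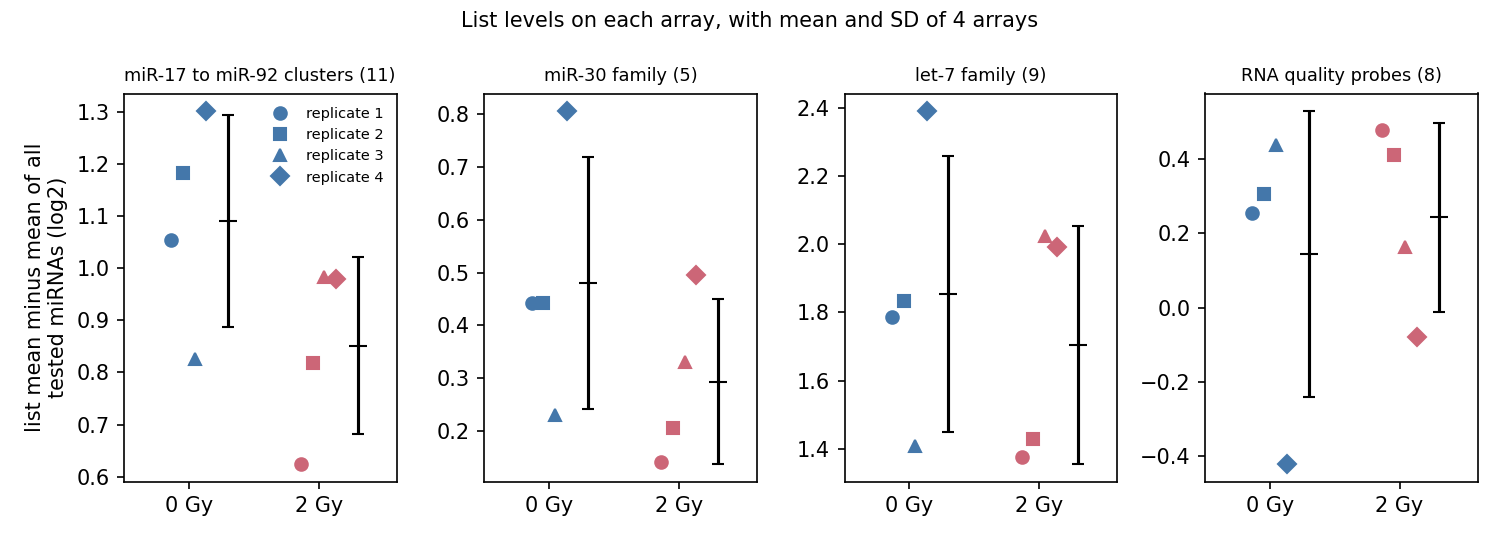
Level of 4 lists on each array (vertical axis, mean of the tested members minus the mean of all tested miRNAs, log2 units; each panel has its own range), by dose, with symbols for the replicate number and bars for mean and SD of 4 arrays. The miR-17 to miR-92 level was 0.85 ± 0.17 after 2 Gy and 1.09 ± 0.20 at 0 Gy with overlapping arrays, and non-irradiated replicate 4 is highest in the first 3 panels and lowest for the RNA quality probes.

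Most markers of other cell types were not detected, while miR-126-3p, miR-137 and miR-128-3p were detected on all 8 arrays. None of the 7 blood and 5 muscle markers was detected on any array. Of 6 endothelial and fibroblast markers only miR-126-3p was tested (-0.085), and of 5 neural and liver markers miR-137 (0.025) and miR-128-3p (-0.036) were. The miR-200 family, which maintains the epithelial state, had no member that met the test's detection filter, and miR-200c-3p was detected on 0 of 8 arrays. The RNA quality probes, which tend to brighten or dim with the state of the RNA, had 8 of 8 tested members above 0, with miR-1225-5p at 0.31, miR-638 at 0.26, miR-1207-5p at 0.26 and miR-1202 at 0.23. Without non-irradiated replicate 4 these 4 were at -0.035, 0.065, 0.078 and 0.085. Without non-irradiated replicate 3 the changes of miR-1225-5p, miR-638 and miR-1207-5p were 0.53, 0.42 and 0.40, and without irradiated replicate 1 they were 0.15, 0.13 and 0.13. The median of the 8 RNA quality probes was 0.15 relative to all tested miRNAs (camera adjusted p = 0.510). Of the 8, 6 lay above the median of all and 2 below. Of all 13 lists camera called 2. Fry called 1, the 14q32 cluster, and camera with an estimated correlation called 0. The number called was 1 without irradiated replicate 2, 3 without non-irradiated replicate 2, 5 without non-irradiated replicate 3, non-irradiated replicate 4 or irradiated replicate 4, and 6 without irradiated replicate 1 or irradiated replicate 3.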

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

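Within groups of 4 arrays, 6 of 148 sets of values held an array whose gap to its nearest neighbour took up nearly the whole range of the group (Dixon's test), where chance gives 5% of sets, so the number of such arrays is near that of chance. MiR-210-3p stood at 6.36 on irradiated replicate 1, against 5.59 to 5.71 on the rest of its group. MiR-4284 stood at 11.2 on irradiated replicate 4, against 10.6 to 10.7. MiR-31-5p was 9.31 on irradiated replicate 4, against 8.69 to 8.75. MiR-29a-3p was 10.2 on irradiated replicate 1, against 10.39 to 10.42. MiR-30c-5p was 7.31 on non-irradiated replicate 4, against 6.77 to 6.85. MiR-376c-3p was 5.07 on that array, against 4.81 to 4.84, close to the floor of 4.75.

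For miR-210-3p the distance of irradiated replicate 1 was traced to its spots. Both of its 2 probes put that array apart (gaps of 0.838 and 0.845 of the range), which argues against a single aberrant probe. On that array 20 spots were unflagged, and the wider of the spreads between spots of a probe was 0.252 log2 units, which argues against few or flagged spots. The higher level may therefore belong to the RNA of that replicate, from its culture or its handling, and the data hold no measure that parts these. Without that array the log2 change after irradiation was 0.53 (adjusted p = 0.233). Over all alternatives the change of miR-210-3p ran from 0.36 (normexp) to 0.79 and the adjusted p from 0.0678 to 0.721. No biological explanation was tested for an array within a group, and the induction of this miRNA by low oxygen is background only.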

How the results depend on the processing

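Array weights, the main axis as a covariate and leaving out both arrays numbered 4 were chosen after the data had been seen. No miRNA passed adjustment in 22 of 23 alternatives, and with array weights 2 did, miR-99b-5p (0.37, adjusted p = 0.0324) and miR-21-3p (-0.44, adjusted p = 0.0350). Of 67 named miRNAs 43 kept their direction in every alternative run, and over all of them 1469 of 1541 values did. Part of these values could not turn. The replicate block, trend, robust eBayes, the axis covariate and the 2 other detection filters leave each log2 change as it was. The tally therefore overstates how stable the directions are. The number at an unadjusted p under 0.05, 22 as reported, was 9 with the percentile over all probes, 14 with quantile normalization, 6 with centring, 14 in the authors' table, 61 with the main axis as a covariate and 38 with array weights. It ran from 14 (without non-irradiated replicate 1) to 38 (without non-irradiated replicate 3) when 1 array was left out, and fewer arrays are part of that change. The axis covariate was drawn from the deviations within groups of these same values. It leaves every log2 change as it was and only lowers the spread within groups, so its p are too small. The 61 is therefore no sign of more changed miRNAs. The difference in miRNAs detected, -12, kept its sign and stayed short of the threshold in all 10 alternatives.

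The miR-17 to miR-92 list kept its camera call in all but 2 alternatives, camera with an estimated correlation (-0.28, adjusted p = 0.172) and fry, which tests the members against no change (own median -0.19, adjusted p = 0.146). Its adjusted p ran from 2.41e-42 without a detection filter, where mostly undetected miRNAs form the background, to 0.172. Its value of -0.28 was -0.17 with normexp, -0.16 with array weights and -0.19 without both arrays numbered 4, and ran from -0.35 (without non-irradiated replicate 3) to -0.15 (without non-irradiated replicate 4) when 1 array was left out, with -0.18 without irradiated replicate 1. The miR-30 family lost its call with the software's total signal (-0.20), in the authors' table (-0.24), with trend (-0.16), with the estimated correlation (-0.16) and with fry (own median -0.062, adjusted p = 0.239), and its value relative to all ran from -0.25 to -0.13 when 1 array was left out. The number of lists called, 2 as reported, was 6 with normexp, 1 with the software's total signal, 1 in the authors' table, 6 without a detection filter, 1 with trend, 4 with array weights, 4 without both arrays numbered 4, 0 with an estimated correlation and 1 with fry. It ran from 1 (without irradiated replicate 2) to 6 (without irradiated replicate 1 or 3), and was 3 without non-irradiated replicate 2 and 5 without non-irradiated replicate 3, non-irradiated replicate 4 or irradiated replicate 4. The let-7, miR-15 and miR-16, and miR-29 families were called lower besides without non-irradiated replicate 3, irradiated replicate 3 or irradiated replicate 4, the miR-221, miR-99, 14q32 and DNA repair lists higher without non-irradiated replicate 4 or irradiated replicate 1, and the miR-221 list also without non-irradiated replicate 2 or irradiated replicate 3. The cause was not tested. Signal over background limits the 376a and 376c members of the 14q32 cluster, with 56.4% and 35.6% of spots at the floor.

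The labels do not say that arrays with the same replicate number belong together. In both slide rows the number is also the slide column, so a shared culture or day cannot be told apart from position along the slide. Deviations from the group means correlated at 0.571, 0.493, -0.667 and 0.845 for numbers 1 to 4, and 4 of 8 arrays correlated best with their own number, a hint from the data and not the design. The replicate block is therefore also a block by slide column. With this block 0 miRNAs passed adjustment, 22 had an unadjusted p under 0.05 and 4 lists were called.

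Some directions turned, none of them past a threshold on either side, and the cause was not tested. Values are log2 changes, or for a list its median minus that of all tested miRNAs with the direction taken from the list test. With the 75th percentile over all probes these were -0.050 for miR-194-5p, -0.043 for let-7c-5p, -0.015 for miR-23a-3p, -0.058 for miR-23b-3p, -0.012 for miR-125b-5p, -0.025 for miR-31-5p, -0.062 for miR-100-5p, -0.026 for miR-181a-5p, -0.071 for miR-27b-3p, -0.036 for the miR-23, miR-27 and miR-24 clusters list. With quantile normalization these were -0.057 for miR-194-5p, -0.035 for let-7c-5p, -0.033 for miR-23b-3p, -4.8e-04 for miR-125b-5p, -0.034 for miR-100-5p, -0.075 for miR-181a-5p, -0.0034 for miR-7975, -0.055 for miR-1260a, -0.046 for miR-27b-3p. Centred on the tested miRNAs these were -0.064 for miR-194-5p, -0.057 for let-7c-5p, -0.029 for miR-23a-3p, -0.071 for miR-23b-3p, -0.026 for miR-125b-5p, -0.039 for miR-31-5p, -0.075 for miR-100-5p, -0.040 for miR-181a-5p, -0.0054 for miR-7975, -0.0083 for miR-5100, -0.084 for miR-27b-3p. With normexp these were 0.010 for miR-140-3p, 0.067 for miR-30e-3p, 0.026 for miR-30d-5p, 0.013 for miR-30c-5p, -0.041 for the miR-23, miR-27 and miR-24 clusters list. With the software's total signal these were -0.040 for miR-194-5p, -0.042 for let-7c-5p, -0.032 for miR-23b-3p, -0.019 for miR-31-5p, -0.048 for miR-100-5p, -0.053 for miR-27b-3p, -0.10 for the regulators of DNA repair genes list. In the authors' table these were -0.0047 for miR-185-5p, -0.017 for miR-194-5p, -0.023 for miR-23b-3p, -0.097 for miR-181a-5p, -0.036 for miR-27b-3p, -0.059 for the p53-linked list, -0.13 for the regulators of DNA repair genes list. Without a detection filter these were -0.018 for the miR-23, miR-27 and miR-24 clusters list, -0.045 for the regulators of DNA repair genes list, 0.15 for the RNA quality probes list. With array weights these were 0.023 for the p53-linked list, 0.022 for the RNA quality probes list. Without both arrays numbered 4 these were 0.0085 for let-7i-5p, -0.0023 for miR-1260a, -0.017 for miR-27b-3p, 0.049 for the p53-linked list. Fry, which tests members against no change, put higher the p53-linked list (own median 0.032, and -0.064 relative to all) and the inflammation and NF-kB list (own median 0.069, and -0.028 relative to all). Leaving out 1 array in turn gave ranges of -0.0029 to 0.13 for miR-194-5p, -0.26 to 0.061 for let-7a-5p, -0.18 to 0.072 for let-7i-5p, -4.3e-05 to 0.21 for miR-27a-3p, -0.038 to 0.21 for miR-23a-3p, -0.051 to 0.13 for miR-23b-3p, -0.18 to 0.037 for miR-29b-3p, -0.11 to 0.0057 for miR-30d-5p, -0.18 to 0.063 for miR-30c-5p, -0.076 to 0.20 for miR-31-5p, -0.027 to 0.10 for miR-100-5p, -0.24 to 0.64 for miR-494-3p, -0.035 to 0.53 for miR-1225-5p, -0.36 to 0.72 for miR-7641, -0.070 to 0.075 for miR-27b-3p, -0.18 to 0.088 for the p53-linked list, -0.27 to 0.032 for the let-7 family list, -0.14 to 0.16 for the miR-23, miR-27 and miR-24 clusters list, -0.13 to 0.097 for the regulators of DNA repair genes list, -0.18 to 0.065 for the inflammation and NF-kB list, -0.043 to 0.20 for the RNA quality probes list.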

Other observations

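The tests of slide position, labelling and RNA quality, that of the miR-17 to miR-92 level per array, and that of the miR-30 family over other splits, were chosen after the patterns had been seen.

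Both arms passed the detection filter for 13 hairpins. The arms of 4 of them went in opposite directions after 2 Gy, as in miR-30a, whose 5p arm changed by -0.088 and 3p arm by 0.19. Among the 4 were miR-22 and miR-224, each with an arm near 0 and many spots at the floor. These arms were miR-22-5p (-0.019, 65.4% of spots) and miR-224-3p (-0.0088, 69.7%). In miR-193b, another of the 13 hairpins, 94.1% of the spots of the 5p arm lay at the floor. The floor holds such changes near 0 and limits the count of directions. In miR-21 the 3p arm changed by -0.36 and the more abundant 5p arm by -0.12, and in miR-17 the 3p arm changed by -0.22 and the 5p arm by -0.045. Both arms of miR-324 were higher, at 0.14 and 0.17. These hairpins were picked after their values were seen. The hypothesis that arms change together, as a change in transcription of the hairpin may bring, was tested across hairpins. Spearman's rho was 0.352 and Pearson's r 0.399 (permutation p of rho = 0.237, 13 hairpins), so the data neither show nor exclude it. Hairpins are not independent replicates here, as all were measured on the same 8 arrays.

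Chance cannot be excluded for the number of miRNAs at an unadjusted p under 0.05 or for the number of lists called. The 8 arrays can be split into 4 and 4 in 35 ways. Past adjustment the real split gave 0 calls and the highest other 47, and since all 35 splits give at least 0, that count tests nothing. The real split gave 22 miRNAs at an unadjusted p under 0.05, 9 of the 35 splits gave as many, and the highest other gave 124. Camera called 2 lists in the real split, 27 of 35 splits called as many, and the highest other called 10. For the lower miR-30 family chance cannot be excluded either, as 2 of 35 splits gave a camera p as small as the real 0.00444, the smallest other being 0.00213. The split with 47 calls sets non-irradiated replicates 1 and 3 and irradiated replicates 1 and 2 against the rest, with both doses on either side. It parts the arrays along the main axis of variation described below, with axis scores of 0.115 to 0.453 against scores of -0.642 to 0.073. The split by slide columns, the first pair of columns against the last, called 0 miRNAs after adjustment and 4 lists.

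The lower miR-17 to miR-92 clusters were picked from 13 lists for their small p. Camera's p was the smallest of the 35 splits in the real one (1 of 35), at 1.99e-08 against 2.18e-06 in the next. Chance alone gives that rank in under 5% of cases for a list named beforehand, while this one was picked from 13. Splits that mix the doses also gave the list small camera p, such as 2.33e-06 and 3.26e-06. In these 2 splits each side held more arrays of 1 dose than of the other. They keep part of the real contrast, so a true change would also lower their p. Where each side held as many arrays of either dose, camera's p ran from 1.18e-04 to 0.9998. Balanced splits thus gave camera p down to 1.18e-04, so a small camera p for this list is no sign of irradiation by itself. By the list level per array, however, 4 of 35 splits gave a difference as large as the real 0.240, the highest other being 0.319, so chance is not excluded on that scale. The list median relative to all miRNAs, -0.284 as reported, was -0.281 in the authors' table. With quantile normalization it was -0.263 (-0.326 to -0.200, 2 standard errors either way). These small shifts argue against the choice of scaling as the whole cause on these arrays. After the slope on the axis loading was removed, the median was -0.197 (-0.266 to -0.127). Both intervals take the list members as independent, although all were measured on the same arrays, so they leave out variation between arrays. Whether the remaining -0.197 exceeds that variation was not tested. The main axis between arrays as the whole cause therefore stays open. Slide row stays open, since 0 rows held both groups, and cannot be told apart from a response to irradiation, which stays a hypothesis.

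Arrays of the same group differed mainly along a single axis, which held 81.7% of the variance within groups. Scores were highest for non-irradiated replicate 3 (0.453) and lowest for non-irradiated replicate 4 (-0.642) and irradiated replicate 4 (-0.409). Levels of miR-6785-5p spanned 3.80 log2 units between these non-irradiated arrays, from 6.74 to 10.5, and miR-5787, miR-7641 and miR-494-3p went along, while miR-26b-5p, miR-96-5p, miR-424-5p and let-7g-5p went the other way. Across miRNAs the axis loading and the log2 change after 2 Gy correlated at 0.416, although miRNAs are not independent replicates.

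Technical readings of this axis were set against the data, and no biological explanation was tested, as the design names no group along it. RNA quality is a candidate source, since the 8 tested RNA quality probes had a median loading of 0.940, at percentile 98.7 of 10000 random lists matched on mean signal (middle 95% from -0.186 to 0.833), with the sign of the axis set by this list. These probes vary together (camera's estimated correlation 0.753), which the random lists were not matched on. Mean loadings were 1.03 for this list, -0.652 for the let-7, -0.627 for the miR-15 and miR-16 and 0.073 for the miR-221, miR-222 and miR-181 families. The percentile is therefore not specific to RNA quality. Labelling yield stays open. The score correlated with the labelling spike-in signal, both centred within groups, at r = -0.660 (exact permutation p = 0.0776, Benjamini-Hochberg 0.310 over 4 relations). Spearman's rho was -0.714 (exact permutation p = 0.0576). Without the 2 arrays farthest from the median r was -0.343, so the relation was weaker without them but kept its sign. Position along the slide stays open as well. The score differed by 0.311 on average between the 2 arrays of a slide column, which also share a replicate number. Of the 24 pairings across rows, 7 gave a difference as small.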
